A study of Mus musculus with 3 samples.

How the data were processed

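Single-cell RNA sequencing was performed on cells digested from the hindlimb knee joints of male C57BL/6J mice, an inbred laboratory strain. Young mice were 3 months old and aged mice were 24 to 28 months old. Per the labels' protocols, each mouse received a daily intraperitoneal injection for 1 month of either vehicle or SW033291 (SW) at 5 mg/kg. SW033291 is a small-molecule inhibitor of 15-hydroxyprostaglandin dehydrogenase, the enzyme that inactivates prostaglandin E2. Joints were trimmed to about 1 mm of tissue at the bone ends and digested with pronase for 1 h and then with liberase for 6 h. The cells were fixed and barcoded with the Evercode WT Mega kit, which marks cells by rounds of pooling in wells rather than by droplets.

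The deposited values were transcript counts, given as unique molecular identifiers (UMIs) per cell and gene, in 16 matrices with 1 table of cells each. Per the file headers the reads were assigned to mm39, and the submitters' processing notes name mm39 and GRCm39. The aligner, the gene annotation and the authors' rule for keeping cells are not given in the sources used here. Per the labels' protocols every sample was pooled into each of 3 sequenced sublibraries, so that no single library belongs to 1 condition. The deposited matrices already hold the separate samples. Their groups were taken from the age, treatment and number in the authors' names of the matrices, which match the 4 groups of the study's design. This rests on those names alone, because the library labels give no group. There were 4 matrices in each of the groups young vehicle, young SW, aged vehicle and aged SW, and each is called a joint sample here. Each table of cells gives its matrix a sample name of its own, but nothing in the labels says that the 16 came from separate mice. The p-values therefore measure the spread between these samples, part of which may be technical.

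The matrices number 56941 genes, and the files used here do not pair these numbers with gene names. Cell types could therefore not be named. The tests planned on chondrocytes, the gene lists, the level of the gene for the inhibited enzyme and the exclusion of blood cells were void. The design fixed before the data were examined provided for this case. The same tests were run on all cells of a sample summed, and on clusters of cells known only by number. At most 2 gene numbers that rose and 2 that fell are named, namely those with the largest change among genes with an adjusted p under 0.05 and a mean above 10 CPM (counts scaled to 1000000 per library).

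All 39827 cells were kept. The smallest count was 850 UMIs, so the planned minimum of 500 UMIs removed no cell. In every cell the UMIs of the matrix summed to the transcript count in the deposited table of cells, once a single stored zero per matrix had been dropped. Doublets were scored per sample with scrublet as implemented in scanpy 1.11.5. Its automatic threshold marked under 0.5% of cells in 12 of the 16 samples, but 22.5% in aged vehicle sample 1, 23.1% in aged vehicle sample 2, 11.5% in young SW sample 4 and 3.05% in young vehicle sample 1. Such uneven calls could not be used to remove cells. The planned removal was therefore run as an alternative, a departure from the plan decided after the call rates were seen and before any gene was tested. Removal of the highest 6% of doublet scores in each sample was added beside it.

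For clustering, counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, ranked within each sample among genes seen in at least 20 cells, gave 30 principal components. A graph of 15 nearest neighbours was divided with the Leiden algorithm (leidenalg 0.10.2) at resolution 1, which gave 32 clusters, numbered from the most to the fewest cells. Counts were then summed over all cells of a sample, and over the cells of each cluster in a sample with at least 20 such cells. Differences in sums over all cells include changes in the mix of cells. A cluster was tested where at least 3 samples of every group qualified, which 15 clusters did.

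Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, quasi-likelihood test) in a single model with 4 group means. Genes with a Benjamini-Hochberg adjusted p under 0.05 are referred to as called. Counts of genes at an unadjusted p under 0.05 are also given. With no effect, a share of about 0.05 of the genes tested would have such a p, so these counts alone are no sign of an effect. Standard errors were derived from the fold change and the quasi-likelihood F statistic. The share of each cluster among a sample's cells was compared with a two-sided exact permutation test of 4 against 4 samples, adjusted over 32 clusters and 3 comparisons (96 tests). This test has 70 arrangements and its smallest p is 0.0286, so no single cluster could pass the adjustment unless many did. A cluster's share cannot be compared cleanly between groups when the genes that define it differ between them. The cells were therefore clustered again without the 2511 genes called by age in all cells or in any cluster, a step added after the data were seen. Each new cluster was given the number of the original cluster most common in it, and by this map 73.4% of cells kept their cluster number. The cells shared by a cluster and its match were given as a percentage of each, over all samples and in each vehicle sample. Matrix sums and medians per cell were compared between groups with the same exact test.

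The edgeR step was tested on simulated counts with the means, dispersions and library sizes of the all-cell sums, in which 200 of 19009 genes were changed in aged SW against aged vehicle. Over 3 runs, 37.3% of 1.5-fold changes, 91% of 2-fold changes and 99% of 4-fold changes were recovered, in genes above 10 CPM. The permutation test was checked on made-up values with known answers. An age score was computed for each sample from genes called between young and aged vehicle samples alone. A score of 0 is the young vehicle mean and a score of 1 is the aged vehicle mean. Each vehicle sample was scored from genes and means chosen without it.

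Other settings fixed beforehand were DESeq2's size factors and the DESeq2 1.42.0 test, no low-count filter, only the groups compared, the replicate number as a block, cells of at least 1000 UMIs, cells thinned to 1000 UMIs (65 cells below this were left out), each of the 3 sublibrary barcode suffixes alone, a minimum of 50 cells, resolution 2, edgeR on cell counts, and each sample left out in turn. Settings added after the data were seen were the position on the barcoding plate and the median UMIs per cell as covariates, the removal of named samples or clusters, sums thinned to an equal size, and the clustering without age genes. For the position on the plate, the samples were divided in the order of their barcoding wells into 2 sets of 8. This cut was set by the number of samples, since the wells run on without a gap. Each set, called a plate side, held 2 samples of each group.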

Results

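Knee joint cells of young and aged male mice, treated for 1 month with vehicle or with the prostaglandin dehydrogenase inhibitor SW033291 (SW), were profiled as UMI counts per cell. There were 39827 cells in 16 joint samples, 4 in each of the 4 groups. The number of cells per sample ranged from 843 in aged SW sample 4 to 3901 in aged SW sample 2. Total UMIs per sample ranged from 6831413 to 62717661, in aged SW sample 4 and young vehicle sample 4. The median per cell lay between 5404 UMIs in aged vehicle sample 4 and 12059 UMIs in young vehicle sample 4. Mean cells per sample were 2292 ± 1434 (SD, n = 4) in aged SW and 2556 ± 1246 in aged vehicle joints. They were 2483 ± 984 in young SW and 2626 ± 1114 in young vehicle joints. Neither cells nor UMIs differed between the groups compared by more than the spread between samples, with exact permutation p values between 0.486 and 0.971 over 12 two-sided tests. Genes are known only by number here, so the comparisons concern counts of genes and clusters of cells without a cell type.

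The first comparison concerned age and set the 4 aged vehicle samples against the 4 young vehicle samples. Age separated the joints in summed expression. The first principal component of the 16 samples, 32.2% of the variance, placed every aged sample on one side and every young sample on the other, whichever treatment they had received. In all cells summed, 950 of 19009 genes were called by edgeR's quasi-likelihood test, 440 higher and 510 lower in aged joints. Of these, 279 were more than 2-fold higher and 251 more than 2-fold lower. The median log2 fold change was 1.22 among the genes that rose and −0.99 among those that fell. The called genes had the same sign in both sets of 8 samples on the barcoding plate for 950 of 950, although they had been chosen in the 16 samples together. Within each set, with 2 samples per group and the spread estimated over all 16 samples together, edgeR called 200 and 233 genes. The balance of directions differed, with 116 higher and 84 lower in aged joints in the first set, and 41 higher and 192 lower in the second.

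**Figure D1:**
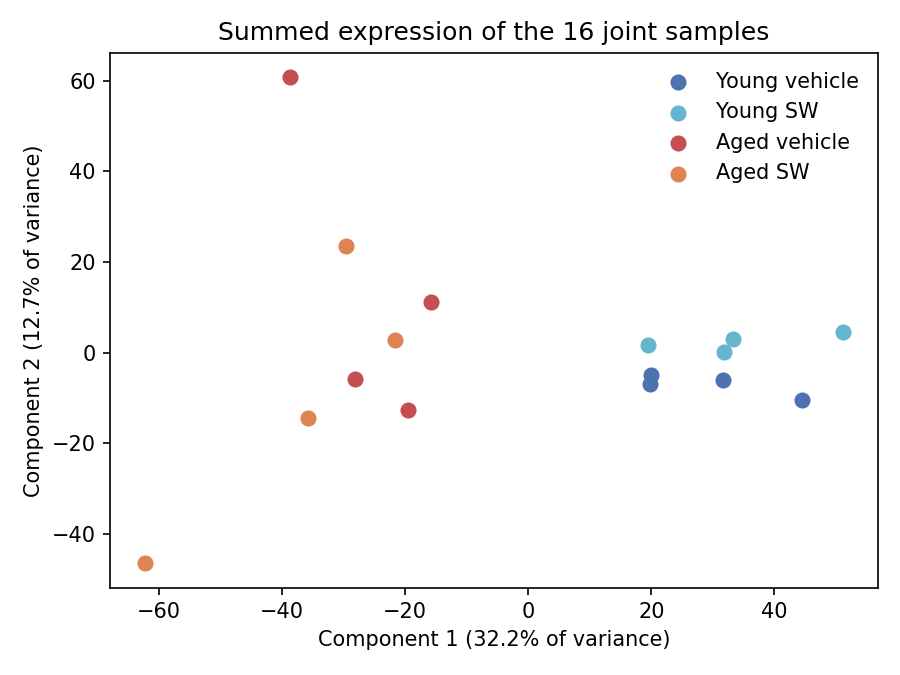
Principal components of log2 CPM over all cells summed, with component 1 (32.2% of the variance) on the horizontal axis and component 2 (12.7%) on the vertical axis. Each point is a joint sample and its colour is its group; young and aged samples lie on opposite sides of component 1, vehicle and SW samples of an age overlap along it, and on component 2 the 4 young SW samples lie above the 4 young vehicle samples, a difference that was not tested.

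The gene number with the largest rise, 2323, measured 82.1 ± 26.3 CPM (SD, n = 4) in aged vehicle and 14.6 ± 7.14 CPM in young vehicle joints. Its log2 fold change was 2.50 (SE 0.45, edgeR adjusted p = 0.00301), and its call ended with the cells of sublibrary suffix 2 alone (2.61, edgeR adjusted p = 0.0581) or suffix 3 alone (1.46, edgeR adjusted p = 0.0758). Gene number 46050 rose from 7.12 ± 2.23 to 37.1 ± 14.0 CPM, a log2 fold change of 2.38 (SE 0.36, edgeR adjusted p = 8.74e-04). Gene number 5374 showed the largest fall, from 127.9 ± 144.9 CPM in young vehicle to 2.21 ± 0.65 CPM in aged vehicle joints, a log2 fold change of −5.86 (SE 0.73, edgeR adjusted p = 1.93e-04). Its young mean depended on young vehicle sample 1, at 345 CPM against 46.0 to 60.9 CPM in the other young vehicle samples. Without that sample the log2 fold change was −4.67. Gene number 3435 fell from 86.4 ± 61.0 to 5.43 ± 1.83 CPM, a log2 fold change of −4.07 (SE 0.40, edgeR adjusted p = 2.46e-05), or −3.45 without the same sample, which measured 178 CPM. In SW-treated joints these 4 genes lay near the vehicle level of their age. Aged SW joints measured 96.4 ± 62.1, 34.2 ± 11.5, 1.47 ± 0.92 and 4.96 ± 1.31 CPM of the 4 gene numbers in the order above. Young SW joints measured 16.03 ± 9.91, 11.7 ± 5.59, 109 ± 83.9 and 77.8 ± 25.7 CPM. Sums over all cells also change with the mix of cells. Gene numbers 5374 and 3435 were highest in young vehicle sample 1 and young SW sample 3, the latter at 233 and 114 CPM. The same samples held the highest shares of cluster 12 in the original clustering, 13.9% and 9.1%. Whether the falls reflect fewer cells of some kind or lower expression within cells was not tested.

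The number of age calls and their balance depended on single samples. There were 587 calls without aged vehicle sample 2 (257 higher, 330 lower) and 580 without young vehicle sample 1 (248 higher, 332 lower). Without young vehicle sample 4 there were 665, with 227 higher and 438 lower, and without aged vehicle sample 3 there were 855, with 445 higher and 410 lower. The number of age calls was 398 after each cell was thinned to 1000 UMIs, and between 398 and 578 with the cells of a single sublibrary suffix.

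The number of age calls differed between the clusters of joint cells. Of the 15 clusters tested, 13 held at least 1 gene called between aged and young vehicle samples. Cluster 1, with 3747 cells or 9.41% of all cells, held 1467 called genes, 742 higher and 725 lower in aged joints. It held 1055 to 1365 with 1 vehicle sample left out. Cluster 7 (2285 cells) held 314 genes, cluster 9 (1701 cells) 166, cluster 3 (3261 cells) 140, cluster 13 (1323 cells) 112 and cluster 11 (1522 cells) 102. Cluster 2, with 3324 cells close to cluster 1 in size, held 17, and cluster 6, with 2440 cells, held 4. Clusters 16 and 17 held 0 by edgeR and by DESeq2, with 35 and 423 genes at an unadjusted p under 0.05 in edgeR, and clusters 8 and 15 held 3 each. In clusters 4, 5 and 10 the counts were 54, 53 and 43. Apart from cluster 1 these counts depended on single samples, and the order of the clusters with them. Without aged vehicle sample 2, clusters 2, 3, 4, 5, 9, 10, 11 and 13 held 8, 61, 5, 31, 64, 6, 59 and 30. Without aged vehicle sample 3, clusters 3, 5, 7, 10, 11 and 13 held 43, 23, 175, 28, 58 and 39. Leaving out young vehicle sample 1 gave 52, 17, 31, 175, 102, 18, 61 and 37 in clusters 3, 4, 5, 7, 9, 10, 11 and 13. Leaving out young vehicle sample 2 gave 6, 110, 22, 53 and 69 in clusters 4, 9, 10, 11 and 13. Leaving out young vehicle sample 4 gave 8, 35, 204, 26, 64 and 13 in clusters 2, 5, 7, 10, 11 and 13. With any 1 vehicle sample left out, clusters 6, 8 and 15 held at most 6, 6 and 8. Each of these 3 held 0 without aged vehicle sample 1, and also without some other single samples. DESeq2 called more in clusters 2, 4, 5, 6, 8, 9, 10 and 15, at 52, 147, 98, 10, 14, 254, 80 and 25. Without the low-count filter edgeR called 204, 155, 116, 180, 2 and 114 in clusters 2, 6, 8, 15, 16 and 17. In clusters 3, 4, 5, 9, 10, 11 and 13 it then called 492, 438, 279, 349, 230, 283 and 313. Such counts alone do not show that many age genes lie there, because no splits of samples were run for them. Without the filter, aged SW against aged vehicle also gave 21, 147, 17, 74, 3 and 28 calls in clusters 2, 6, 8, 15, 16 and 17. In clusters 3, 4, 5, 9, 10, 11 and 13 it gave 18, 58, 46, 50, 54, 19 and 32, fewer than age did. Over all clusters 1906 genes were called, 363 of them in at least 2 clusters, and 329 of the 363 moved in the same direction in every cluster that called them. The 2478 pairs of gene and cluster became 1572 without aged vehicle sample 2 and 1592 without young vehicle sample 1. The summed library of a cluster limits its calls. The median library was largest in cluster 4, at 3448013.5 UMIs. It was 2672470 UMIs in cluster 1, 1956176 in cluster 2 and 195479 in cluster 16. With all sums thinned to 238000 UMIs per sample, cluster 1 had 12 calls, cluster 7 had 15, cluster 11 had 4, cluster 10 had 2 and the other 6 clusters that kept enough samples had 0.

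**Figure D2:**
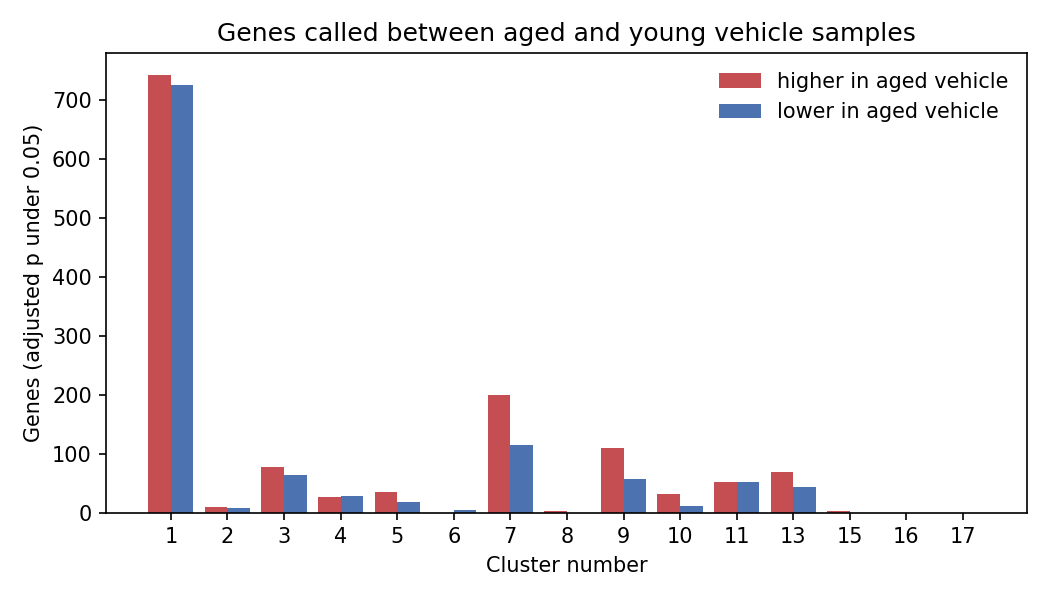
Number of genes with an edgeR adjusted p under 0.05 (vertical axis) in each of the 15 clusters tested (horizontal axis), as bars for genes higher and lower in aged than in young vehicle samples. Cluster 1 holds 742 higher and 725 lower genes, and no other cluster holds more than 314 in all.

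The shares of cells per cluster were compared between the same samples. When the cells were clustered without genes called by age, the shares of 4 clusters did not overlap between aged and young vehicle samples and had also not overlapped in the original clustering. Cluster 12 made up 0.946% ± 0.401 (SD, n = 4) of aged and 6.31% ± 4.33 of young vehicle samples. Cluster 6 made up 4.51% ± 0.740 of aged and 6.87% ± 1.12 of young vehicle samples. In the other direction, cluster 19 made up 3.98% ± 1.84 of aged and 0.918% ± 0.570 of young samples, and cluster 20 made up 3.81% ± 3.39 and 0.747% ± 0.264. The aged mean of cluster 20 depended on aged vehicle sample 4, at 8.88% against 1.80% to 2.43%, and was 2.12% without it. The young mean of cluster 12 depended on young vehicle sample 1, at 12.7%, and was 4.17% without it. For each of the 4 clusters the exact permutation p was 0.0286, the smallest this test can give, and the adjusted p was 0.421, so that no cluster passed the adjustment. With 1 vehicle sample left out the exact permutation p rose to 0.0571 for cluster 6 (without aged sample 1, 3 or 4 or young sample 1 or 4), cluster 12 (any aged) and cluster 19 (any young), and to 0.114 for cluster 20 (any young). Shares that do not overlap cannot come to overlap once a sample is left out. The rise means only that other arrangements of the samples left had as large a difference of means. Chance alone gives a lack of overlap in 2.86% of clusters, or 0.91 of the 32. In the original clustering 9 clusters did not overlap (adjusted exact permutation p = 0.274), and the clusters matched to the other 5 overlapped once the age genes were left out. Of the 5, cluster 21 made up 2.27% of aged and 0.850% of young vehicle samples, close to its original 2.19% and 0.819%, and overlapped only between young vehicle sample 3 (1.58%) and aged vehicle sample 2 (1.53%). The clusters matched to 5 and 11 were still higher in aged samples, at 8.26% against 5.17% and 4.71% against 1.94% (exact permutation p = 0.0571 for each of the 3). The clusters matched to 9 and 10 measured 3.96% against 4.61% and 9.82% against 9.81%, where clusters 9 and 10 had originally measured 1.57% against 6.66% and 2.82% against 5.23%. These 4 matched clusters held many other cells. Only 46.4%, 32.6% and 59.8% of the cells matched to clusters 9, 10 and 11 came from them, and 45.8% of the cells of cluster 5 stayed together, so the overlap is not that of the same cells. By an edgeR test of cell counts in the original clusters, 7 clusters differed with age at an adjusted p under 0.05, among them clusters 12, 19 and 20.

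**Figure D3:**
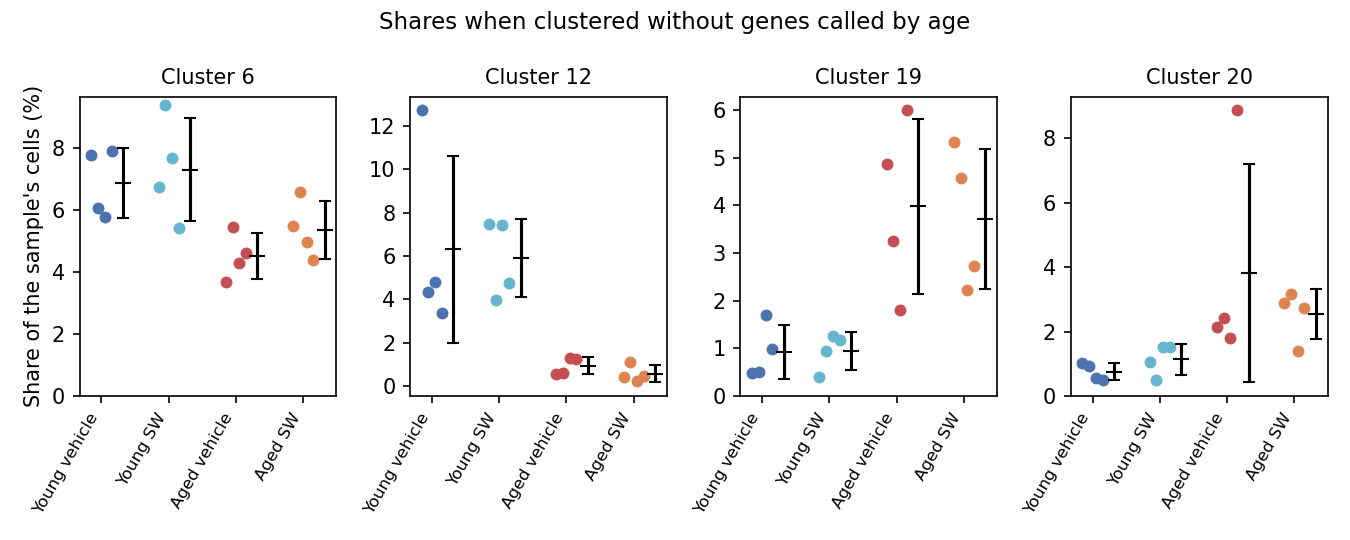
Share of each sample's cells (%, vertical axes) in clusters 6, 12, 19 and 20 by group, when clustered without genes called by age. Points are joint samples, and the bars beside them give the mean and SD of 4 samples; the aged and young vehicle samples do not overlap in any of the 4 panels.

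The second comparison asked what inhibition of the dehydrogenase changed in aged joints, with the 4 aged SW samples set against the 4 aged vehicle samples. No gene was called in all cells summed. By edgeR's quasi-likelihood test the count was 0 of 19009, the smallest adjusted p was 0.929 and 958 genes had an unadjusted p under 0.05. Without aged SW sample 2 edgeR called 0, with 2334 genes at an unadjusted p under 0.05. The aged SW samples left then had median UMIs per cell of 6144 to 7592. Those of aged vehicle samples 1, 2 and 3 were 8686 to 10996, and that of sample 4 was 5404. Depth and treatment were thus partly confounded. With all samples DESeq2 also called 0. In each of the 15 clusters edgeR called 0 genes, with the smallest adjusted p, 0.0536, in cluster 9, where 566 genes had an unadjusted p under 0.05. DESeq2 called 8 over all clusters. With 1 sample left out, edgeR called 12 pairs of gene and cluster without aged vehicle sample 3, 11 without aged SW sample 2, 3 without aged vehicle sample 1, and 1 without aged SW sample 3 or aged vehicle sample 2. The median standard error of the log2 fold change was 0.134 over 7507 genes above 10 CPM, and the median size of the change was 0.109. In simulated all-cell sums of this comparison, in genes above 10 CPM, the test recovered 91% of 2-fold changes but 37.3% of 1.5-fold changes. Many changes under 1.5-fold were therefore not detectable in these sums at this depth and sample number. Genes below 10 CPM and the smaller sums of the clusters were not simulated, so what could be detected there is not known. Without the low-count filter, edgeR called 684 pairs of gene and cluster, and 15 of 21 splits of the 8 aged samples gave as many, the real split included.

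Cell shares did not separate aged SW from aged vehicle joints either. No cluster reached an exact permutation p under 0.05, and the lowest was 0.143 for cluster 32, a group of 38 cells (adjusted p = 0.549). Cluster 11 made up 3.65% ± 2.85 (SD, n = 4) of aged SW and 7.34% ± 4.25 of aged vehicle samples (exact permutation p = 0.171, adjusted p = 0.582). Its difference of −3.69 percentage points became −1.60 without aged vehicle sample 3. Cluster 2 made up 9.63% ± 2.30 and 7.80% ± 0.644 (exact permutation p = 0.171, adjusted p = 0.582), and its difference of 1.83 became 0.751 without aged SW sample 3.

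Whether treatment moved aged joints toward the young profile was asked in the same samples. Across 19009 genes, which are not independent replicates, the correlation between the SW effect in aged joints and the effect of age was −0.153. Both effects share the aged vehicle samples, and this alone gave −0.490 in simulations with no effect. The difference between aged and young samples stays in the data when the 8 aged samples are named anew. Over the 70 ways of naming 4 of them vehicle, the correlation averaged −0.289 and ranged from −0.558 to 0.0027. The covariance was −0.0227, against −0.0375 ± 0.000925 (SD of 50 simulations) with no effect, a difference of 0.0149. That SD leaves out the spread between aged samples. Over the 70 ways of naming 4 of the 8 aged samples vehicle, the covariance averaged −0.0477 and ranged from −0.126 to 0.000395, and 61 were at or below the observed value. When 2 of the aged vehicle samples were used for each effect, the mean correlation over the 6 ways of dividing them was 0.0875, with a range from −0.0808 to 0.189. Over genes above 10 CPM the correlation was 0.01998. Of the 70 ways of naming 4 of the 8 aged samples vehicle, 60 gave a correlation as low or lower, a one-sided permutation p of 0.857 for a shift toward young. On the age score, aged SW joints lay between 0.859 and 1.11 and aged vehicle joints between 0.783 and 0.966.

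**Figure D4:**
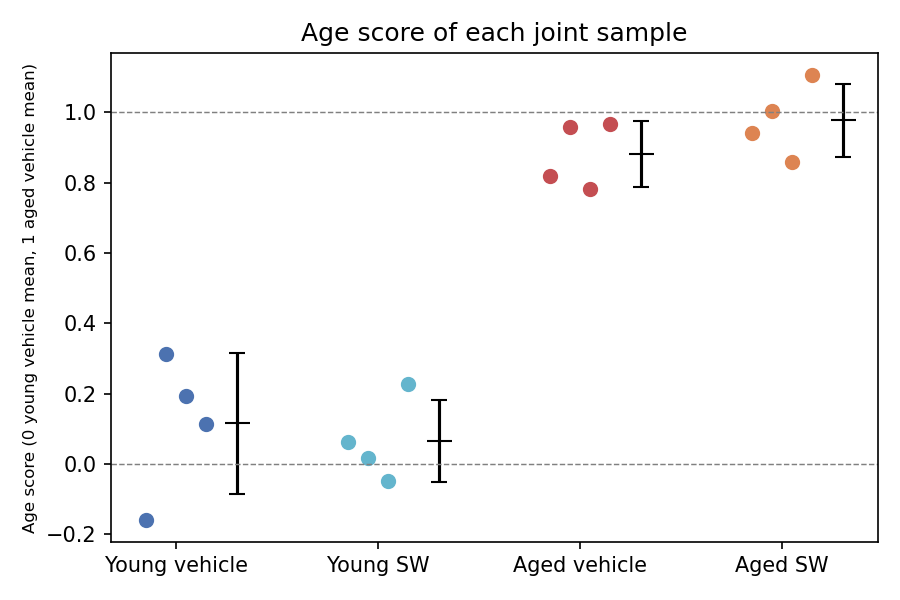
Age score of each joint sample by group (vertical axis, where 0 is the young vehicle mean and 1 the aged vehicle mean), with the mean and SD of 4 samples beside the points. The aged SW samples lie between 0.859 and 1.11 and the young SW samples between −0.047 and 0.229.

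The third comparison set the 4 young SW samples against the 4 young vehicle samples. In all cells edgeR called 0 of 19009 genes, with 553 genes at an unadjusted p under 0.05, and DESeq2 called 0. In the 15 clusters edgeR called 0, and DESeq2 called 1. Cluster 3 made up 5.80% ± 1.98 (SD, n = 4) of young SW and 7.96% ± 0.404 of young vehicle samples. The samples did not overlap (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.274). Young SW sample 3, at 2.86%, made up much of the difference, which was −2.16 percentage points and −1.18 without it. When the cells were clustered without genes called by age, the cluster matched to cluster 3 held 35.8% of its cells and made up 2.59% ± 0.980 and 3.01% ± 0.553 (exact permutation p = 0.486). No other cluster had an exact permutation p under 0.05. Young SW joints lay between −0.047 and 0.229 on the age score, and young vehicle joints between −0.158 and 0.312.

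The interaction of treatment and age tests whether the SW effect differed between aged and young joints. In all cells it called 0 genes by edgeR, with 1165 at an unadjusted p under 0.05, and 2 by DESeq2. Without aged SW sample 2, where depth and treatment were partly confounded in aged joints, 2344 genes had such a p in edgeR. Over the 15 clusters the interaction called 1 gene, in cluster 7, with an interaction log2 fold change of 4.31 (SE 0.75, edgeR adjusted p = 0.0459). The gene was chosen after its values were seen. The call in cluster 7 was lost when aged SW sample 1, aged vehicle sample 2, 3 or 4, young SW sample 1, 2 or 4, or young vehicle sample 1 or 2 was left out. It measured 30.2 ± 26.6 CPM (SD, n = 4) in aged SW, 2 ± 2.7 in aged vehicle, 47.6 ± 19.2 in young SW and 92.4 ± 42.8 in young vehicle samples. No cluster's share showed a different SW effect between the ages after adjustment, by an exact permutation of treatment within each age. The lowest p was 0.0143 for cluster 3 (adjusted p = 0.457), whose share differed by 0.808 percentage points between SW and vehicle in aged joints and by −2.16 percentage points in young joints. The young value was −1.18 without young SW sample 3, and the aged value was 0.119 without aged SW sample 3 and 1.32 without aged SW sample 2. The exact permutation p was at most 0.0449 with any 1 sample left out.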

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

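The tests of cluster 1 with sums of 500000 UMIs and of its order with cluster 7, and the splits of samples for comparisons that called nothing, were chosen only after the result was seen, as were the tests of the cells shared by clusters 6, 12, 19 and 20 with the clusters matched to them.

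Among the 4 samples of a group, 1 sample stood far from the other 3 in 10 of 76 groups of values examined, where chance gives about 3.8 (1 in 20). Young vehicle sample 1 was high for both genes that fell with age, at 345 CPM of gene number 5374 against 46.0 to 60.9, and 178 CPM of gene number 3435 against 54.6 to 58.2. It was also high for the share of cluster 12, at 13.9% against 4.39% to 5.88%. Aged SW sample 2 measured 2.84 CPM of gene number 5374 against 0.89 to 1.08. Gene number 2323 measured 30.8 CPM in young SW sample 4 against 10.3 to 12.6, and 121 CPM in aged vehicle sample 2 against 65.6 to 73.5. The share of cluster 3 was 2.86% in young SW sample 3 against 6.43% to 6.98%, and that of cluster 10 was 1.90% in aged SW sample 2 against 3.92% to 4.21%. Aged vehicle sample 4 held 10.8% of its cells in cluster 20 against 1.91% to 2.77%, and 4.15% in cluster 21 against 1.40% to 1.67%.

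The SW effect differed between aged and young joints for 1 gene in cluster 7, by an interaction log2 fold change of 4.31 in edgeR. Of 40 splits by treatment within age, 20 called as many pairs of gene and cluster, and the highest other split called 11, so chance cannot be excluded for this call.

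The sample names in the tables of cells follow a numbering in which aged SW sample 1 and young SW sample 4 seem out of place, as if their names had been exchanged. An exchange would put aged SW sample 1 near 0 on the age score and young SW sample 4 near 1. They scored 0.943 and 0.229, which argues against an exchange between the ages. A wrong treatment name within an age was not tested. Leaving out both samples gave 880 age calls and 0 SW calls in aged joints by edgeR, with 827 genes at an unadjusted p under 0.05.

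Cluster 1 held 1467 of the 2478 age calls in clusters. A larger summed library may account for part of its excess over clusters with smaller libraries. Cluster 4 had a larger median library, 3448013.5 UMIs against 2672470 in cluster 1, but held 54 age calls. This argues against library size as the cause of the excess over cluster 4. At 500000 UMIs per sample cluster 1 kept 87 calls against 10 in cluster 3, 1 in cluster 2 and 0 by edgeR in clusters 4, 6 and 8. That argues against library size as the whole cause of its excess over these clusters. At 238000 UMIs it had 12 calls and cluster 7 had 15, counts too low to order them, a limit set after the values were seen. At 1000000 UMIs only cluster 4 kept enough samples, with 14 calls, so the test planned at that depth cannot tell. A stronger response to age in the cells of cluster 1 stays open as a hypothesis. Cluster 1 also had the lowest spread between samples of the 15 clusters. Its biological coefficient of variation in edgeR was 0.175, against 0.187 in cluster 7 and 0.197 to 0.285 in clusters 2, 3, 4, 6 and 8. What this lower spread added to its calls was not tested.

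Shares of 9 of 32 clusters did not overlap between aged and young vehicle samples, where chance gives 0.91, and without the genes called by age, which could have drawn the clusters, 4 of the 9 stayed apart. By the rule written before this test, fewer than 50% staying apart counted for the called genes as a cause. By that rule the count came out for that cause over the 9 clusters as a set. It cannot decide the cause, because no clustering without other genes was run for comparison. The count also turned on cluster 21, which overlapped only by young vehicle sample 3 (1.58%) and aged vehicle sample 2 (1.53%). Clusters 6, 12, 19 and 20 were picked because they stayed apart, so that they did is no test. Clusters 6, 19 and 20 shared at least 78.8% of their cells with the matched clusters in each vehicle sample. This argues against the called genes as the whole cause for these 3, but says nothing of genes that were not called. Clusters 12, 19 and 20 were not among the 15 tested for age genes, and cluster 6 held 4 calls. Genes that changed with age only inside these 4 clusters were therefore hardly left out. Cluster 12 shared at least 50% in 6 of 8 vehicle samples and clusters 5, 9, 10 and 11 were matched to many other cells, so the called genes stay open there, while cluster 21 kept 98.2% of its cells and its means (2.27% and 0.850%, originally 2.19% and 0.819%). All 9 stayed apart without the highest 6% of doublet scores, which argues against doublets of high score as the whole cause. Doublets of low score stay in under this removal, so it cannot speak for them. The median doublet score was 0.084 in cluster 19 and 0.089 in cluster 20, against 0.03 in cluster 6 and 0.048 in cluster 12. A difference in cell makeup with age stays open, as do age genes that were not called and a difference in how cells came out of the digestion, neither of them tested.

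For the age comparison, 1 of 35 splits of the 8 vehicle samples, the real one, called as many genes in all cells (950, highest other 1) and as many pairs in clusters (2478, highest other 166). This argues against chance, which would put the real split first in 1 of 35 cases, the least this test can give. For aged SW against aged vehicle the count was 0, which all 35 of 35 splits reach by definition, so the splits carry no information about chance there. The highest other split called 239 genes in all cells and 60 pairs in clusters. Without the low-count filter, 15 of 21 splits called as many pairs as the 684 found (highest other 1754), so chance cannot be excluded for those pairs. The split with 239 calls set aged SW samples 1, 3 and 4 and aged vehicle sample 4 against the rest, which parts the aged samples into those of the lowest and of the highest median UMIs per cell. It points to a structure of the samples, but differs from the treatment split only by exchanging aged SW sample 2 and aged vehicle sample 4, and what it reflects was not tested. For the treatment split with the median UMIs per cell as a covariate, edgeR called 0 genes, with 836 at an unadjusted p under 0.05. Without aged SW sample 2 and without that covariate it called 0, with 2334. Leaving out that sample partly confounds depth with treatment, so the 2334 cannot be told from a depth difference. The splits likewise carry no information about the 0 calls for young SW, with 35 of 35 splits in all cells (highest other 2) and in clusters (highest other 4). The same holds of the 0 interaction calls in all cells, with 100 of 100 splits (highest other 100).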

How the results depend on the processing

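The plate side, the median UMIs per cell, the highest doublet scores, the clusters of few genes, the removal of named samples, the clustering without age genes, its repeats with 1 vehicle sample left out, and the interaction for the share of cluster 3 with 1 sample left out were alternatives chosen only after the result was seen. In all cells, aged SW against aged vehicle gave 0 calls under every alternative run except 3 without the low-count filter (and 1 when compared within 1 plate side, with the spread shared by all samples), and young SW gave 0 under every one. The 950 age calls became 398 with cells thinned to 1000 UMIs, and 578, 398 and 517 with single sublibrary suffixes, where fewer counts are tested. They were 200 and 233 when compared within single plate sides, 580 to 855 with 1 sample left out, and 832 to 1310 under the rest. The interaction gave 2 by DESeq2. Over gene and cluster pairs, no low-count filter gave 684 calls for aged SW, 5178 for age, 484 for young SW and 563 for the interaction. Most lay in genes that the filter keeps, 576 for aged SW and 4592 for age. DESeq2 gave 8, 1 and 3 for aged SW, young SW and the interaction. With 1 sample left out the pairs ranged from 0 to 12 for aged SW, 1572 to 2348 for age, 0 to 1 for young SW and 0 to 5 for the interaction. The interaction call was lost, at 0, with a minimum of 50 cells, with the plate side or the median UMIs as a covariate, and without aged SW sample 1 and young SW sample 4. The cause was not tested.

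Replicate numbers did not pair the samples, with correlations of same-numbered samples from −0.171 to 0.133. With the replicate number as a block, 4 pairs were called for aged SW and 2 for the interaction, and 865 genes for age in all cells. It also moved the age calls of cluster 4 from 54 to 28, of cluster 6 from 4 to 1, and of clusters 8 and 15 from 3 to 0 each by edgeR (512 and 379 at an unadjusted p under 0.05), and beyond these no count by over 1.5 times.

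Clusters whose shares differed at an unadjusted p under 0.05 numbered 9 for age, 4 without age genes, 15 by edgeR and 5 to 9 with 1 sample left out. At an adjusted p edgeR gave 7. For aged SW there was 1 by edgeR and 0 to 1 with 1 sample left out. For young SW the 1 cluster became 0 by edgeR, without doublet calls and with thinned cells, 2 without aged SW sample 1 and young SW sample 4, and 0 to 2 with 1 sample left out. Without age genes the cluster matched to cluster 10, which held 4008 cells against 1598, had a difference of 0.0112 percentage points against −2.40 for cluster 10. Single cluster shares stayed on the same side of an unadjusted p of 0.05 in 169 cases, lost it in 57 and reversed in 1. For shares that did not overlap with all samples, a p over 0.05 with 1 sample left out did not mean that they came to overlap. The 4 gene numbers kept their call in 86 cases, and gene number 2323 lost it in 2, at log2 fold changes of 2.61 and 1.46 with single sublibrary suffixes. Calls per cluster stayed within 1.5 times in 133 cases and moved in 99. The correlation of the SW and age effects was 0.01998 above 10 CPM, 0.0875 with the vehicle samples divided, and −0.256 to −0.114 with 1 sample left out. Alternatives planned for chondrocytes, gene lists, the enzyme's gene and blood cells were not run, because genes have no names here. For tests within clusters, single sublibraries, cell filters, thinned cells, only the groups compared and resolution 2 were not run.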

Other observations

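The sign test across clusters and the comparison of sample structure below were chosen only after the result was seen. Genes called by age in cluster 1 had the same sign in the other clusters tested in 54.7% (cluster 3) to 85% (cluster 13) of cases, whether or not they were called there. Of the 950 genes called by age in all cells, 345 were also called in at least 1 cluster. Cluster 12 drew 92.9% of its cells from young samples and cluster 9 drew 83.4%, while cluster 11 drew 16.4%, with 33.3% of its cells from aged vehicle sample 3 alone. Cluster 16 held 1002 cells with a median of 257 genes, and its most abundant gene took 58.7% of its UMIs. The Spearman correlation of summed expression between samples lay between 0.942 and 0.989, computed across genes, which are not independent replicates.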
